A study of Mus musculus with 2 samples.

How the data were processed

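Small RNA was sequenced from gastrocnemius of female B6CASTF1/J mice at postnatal day 4 in 2 libraries, 1 per female, per the labels. The labels describe RNA below 30 bases. The authors deposited, for each library, raw counts per gene against the mm10 assembly with the GENCODE M21 annotation, per the labels and the text deposited with the files. The aligner and counter and their settings are not given in the sources used here. Each deposited table has 3 count columns, and their sums show reads counted without regard to strand, reads on the gene's own strand and reads on the opposite strand. The deposited counts are whole numbers and were not normalized. Reads that matched several places appear in a separate line of each deposited table and not in any gene, so genes with near-identical copies can be undercounted.

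The 4 lines that name no gene were kept out of library sizes and tests. Of all reads, the own-strand column held 36.9% in the multimapping line, 8.03% in the unmapped line and 1.70% in the line for no feature in library 1, and 37.6%, 9.26% and 2.09% in library 2. The ambiguous line held 0 reads in the own-strand column. It held 700483 reads in library 1 and 513662 in library 2 when strand was ignored, because 64 counted genes overlap another counted gene on the other strand. Of the opposite-strand counts, 99.99% in both libraries lay in those genes. By a rule fixed before the data were examined, the own-strand column was used for every main value. It assigned 53.4% of the reads in library 1 and 51.1% in library 2 to genes.

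All 2202 gene identifiers matched genes of type miRNA in GENCODE M21, which gave the symbols, positions and hosts, and transcript sequences from the same release gave the shared stretches. Levels were CPM of own-strand gene counts. A gene was called detected at 2 CPM or more in both libraries. A pseudocount of 0.5 CPM was used on the log2 scale. Scaling factors came from TMM in edgeR 4.0.16 (R 4.3.3), with DESeq2 1.42.0 size factors and plain totals as alternatives. The coefficient of variation is the square root of edgeR's common dispersion, with an interval from 100 bootstrap draws of genes. Genes were compared between libraries with an exact two-sided binomial test of their counts given the TMM-scaled totals, adjusted by Benjamini-Hochberg with a threshold of 0.05. Ratio and level intervals are exact at 95% and cover counting error only, since reads without molecular identifiers are not independent molecules. The limit for a count of 0 is 3 counts. Other computations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.

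On simulated counts for the 335 detected genes in 2 libraries, the counting test called 89.0% of genes changed 2-fold, 73.0% of genes changed 1.5-fold and 0% of unchanged genes. Those counts held counting error only, with known library totals and no spread between animals. The 0% is therefore no rate of false calls for the real libraries. A simulated coefficient of variation of 0.2 was estimated as 0.201.

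Before the data were examined, 21 gene lists were fixed, and 186 of their genes were in the tables, of which 154 were detected. Of 210 symbols in the lists, 24 were not matched, many of them alternative spellings. The lists cover the myomiRs, the let-7, mir-29, mir-30, mir-181, mir-26 and Mir221-Mir222 families, the mir-23/27/24, Mir17-92, Mir322-Mir503, Dlk1-Dio3, H19-Igf2 and Hox genes, and markers of erythroid, leukocyte, endothelial, smooth muscle, connective, epithelial, neural, and liver and gut cells. The genes named were also fixed by rule: the 20 highest in mean CPM, the 3 highest of each list, and, among genes at 10 CPM or more, the 5 with the largest ratio in each direction that passed the counting test. Other genes were named after their values were seen, namely members of the myomiR and let-7 lists below the top 3, Mir27a, Mir30c-1, Mir30c-2, Mir503, Mir1197 and the genes marked so in the closing section. A list's rank is the percentile of its median level among 10000 random lists of the same size.

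Alternatives fixed before the data were examined were the unstranded counts, detection at 10 CPM or at 1 count in either library, other scaling, pseudocounts of 0.1 and 5, each library alone, ranks among detected genes only, shared stretches of 18 and 24 bases and a neighbour distance of 50 kb. Because the series has 1 group of 2 libraries, no test between conditions and no other split of the samples applied, and leaving out a library gave the values of the other with no test.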

Results

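MicroRNAs (miRNAs) were measured by small RNA sequencing in the gastrocnemius, the large calf muscle of the hind limb, of female mice at postnatal day 4. The animals were B6CASTF1/J, the hybrid offspring of C57BL/6J and CAST/EiJ parents. The data comprised 1 group of 2 libraries, which the labels assign to separately numbered females. Library 1 held 10426665 reads and library 2 held 8487769 reads. Reads assigned to a miRNA gene on its own strand numbered 5569392 in library 1 and 4336759 in library 2. A further 36.9% of the reads in library 1 and 37.6% in library 2 were listed as matching several places and belonged to no gene. With 1 group, no condition could be compared with another, and the values describe this muscle at this age and the spread between its libraries. Levels are own-strand gene counts scaled to library totals as CPM, given as mean ± SD over the 2 libraries unless stated otherwise.

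Mir206, a miRNA gene of skeletal muscle lineage induced during myoblast differentiation, had the most counts of any gene in both libraries. It reached 124329 ± 7080 CPM (SD, n = 2), which was 12.4% of all gene counts. Because multimapping reads belong to no gene, this rank and those below hold for counted reads only. Next came Mir411 at 73057 ± 5406 CPM, a member of the imprinted Dlk1-Dio3 cluster, and Mir378a at 58024 ± 2753 CPM, which lies in an intron of the metabolic coactivator gene Ppargc1b. Mirlet7i followed at 55909 ± 2029 CPM, and Mir335, in an intron of the imprinted gene Mest, at 44684 ± 4075 CPM. Mir21a, a widely expressed gene in an exon of Vmp1, reached 16868 ± 766 CPM, and Mir99a, in an intron of its host transcript Mir99ahg, reached 17919 ± 2832 CPM. The 10 most abundant genes together held 54.1% ± 1.09 (SD, n = 2) of the counts, and the 50 most abundant held 89.5% ± 0.191. Of 2202 counted genes, 335 were detected at 2 CPM or more in both libraries, and 1462 had no count in either library. A count of 0 allowed up to 0.539 CPM in library 1 and 0.692 CPM in library 2. Mir378a overlaps another counted gene on the opposite strand, and its count was 0 when strand was ignored. Mir378a and Mir411 also share 20 and 21 bases with another counted gene, which leaves their levels uncertain.

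The muscle-enriched list, known as myomiRs, held 12.6% ± 0.728 (SD, n = 2) of the counts, and Mir206 alone made up 98.8% of that share. Of 12 listed genes, 9 were detected. Mir499, in an intron of the slow myosin gene Myh7b, reached 1169 ± 173 CPM, and Mir208b, in an intron of the slow myosin gene Myh7, reached 156 ± 43.7 CPM. Mir208a, the counterpart of Mir208b in the cardiac myosin locus, was at 5.43 ± 0.186 CPM. Mir486, a gene in the muscle ankyrin locus Ank1, was at 87.3 ± 10.5 CPM. It shares no stretch of 14 bases or more with another counted gene. Matches within its own locus or outside the counted genes were not searched, so its level is uncertain too. Mir133b, which lies beside Mir206, was at 82.9 ± 4.45 CPM, and the ratio of Mir206 to Mir133b was 1505 ± 166 (SD, n = 2). The remaining classical myomiRs had few counts. Mir1a-2 had 91 counts in library 1 and 77 in library 2, Mir1a-1 had 13 and 9, Mir133a-1 had 25 and 26, and Mir133a-2 had 2 and 2. Mir1a-1 and Mir1a-2 share a stretch of 28 bases, Mir133a-1 and Mir133a-2 share 31 bases, and Mir133b shares 21 bases with Mir133a-1. Reads from these genes can match more than 1 place, so their levels and the ratio of Mir206 to Mir133b are uncertain. Mir206 shares no stretch of 14 bases or more with another counted gene. Its annotated hairpin lies on chromosome 1, plus strand, from 20679010 to 20679082 in mm10, inside an exon of the long noncoding RNA gene Gm28653, and reads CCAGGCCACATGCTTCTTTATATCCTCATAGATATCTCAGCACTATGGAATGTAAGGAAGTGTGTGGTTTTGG.

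The let-7 family, miRNAs that accumulate as tissues mature and repress growth and fetal genes, held 12.4% ± 0.282 (SD, n = 2) of the counts. All 12 listed let-7 genes were detected. Mirlet7i at 55909 ± 2029 CPM and Mirlet7g at 36830 ± 256 CPM led the family, followed by Mirlet7d at 14045 ± 700 CPM and Mirlet7b at 8145 ± 1121 CPM. Mirlet7e was at 3297 ± 254 CPM and Mir98 at 2944 ± 72.7 CPM. The other 6 members, which share 20 bases or more with another counted gene, ranged from Mirlet7a-2 at 78.2 ± 9.76 CPM to Mirlet7f-2 at 1840 ± 94.5 CPM, and their levels are uncertain for that reason. Between the libraries, 5 of the 12 genes were higher in library 2, 3 were higher in library 1 and 4 did not pass the counting test.

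**Figure D1:**
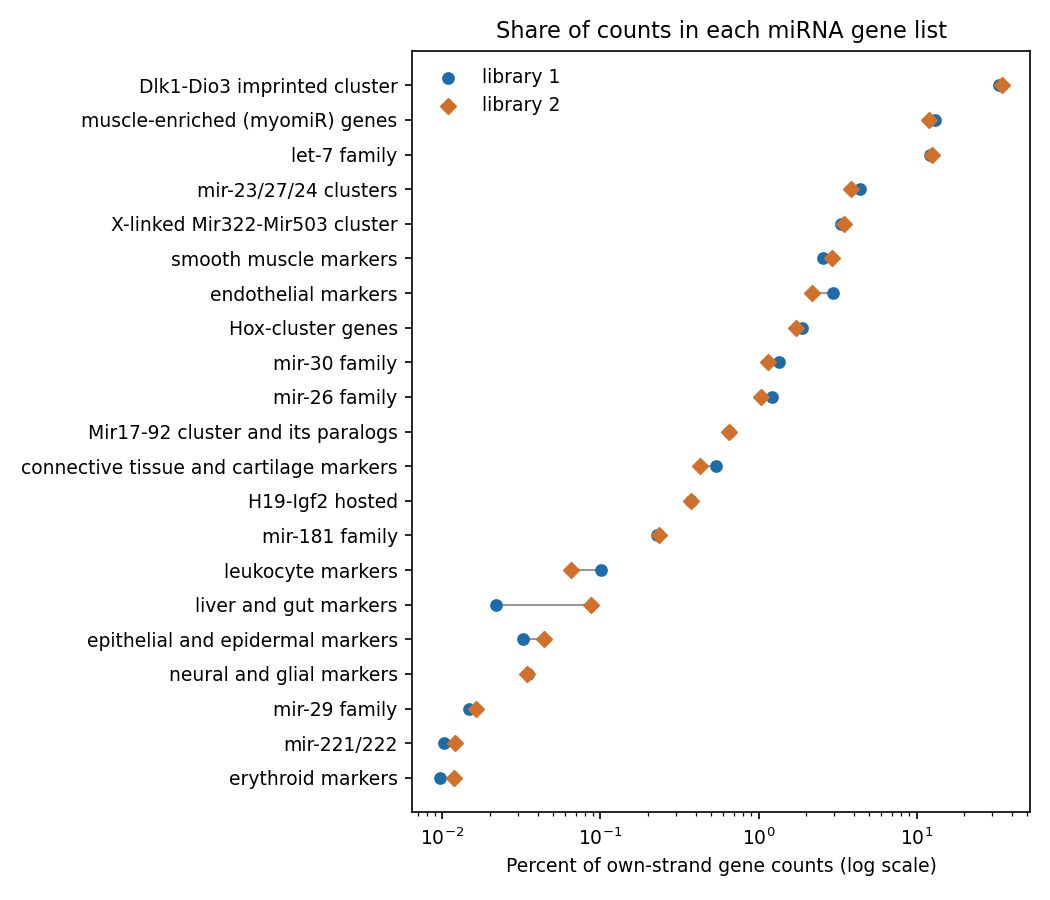
Share of own-strand gene counts (percent, log scale) held by each of the 21 miRNA gene lists, with a circle for library 1 and a diamond for library 2 and a grey line joining them. The Dlk1-Dio3 list is the largest at 33.8% on average, and the liver and gut list shows the widest gap between the libraries.

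Genes of the imprinted Dlk1-Dio3 cluster, which are transcribed from the maternal chromosome, held the largest share of any list at 33.8% ± 1.07 (SD, n = 2). Of 58 listed genes, 53 were detected, and 6 of the 20 most abundant genes in the muscle belonged to the cluster. These were Mir411, Mir487b at 44428 ± 2939 CPM, Mir127 at 44397 ± 788 CPM, Mir379 at 30604 ± 644 CPM, Mir431 at 28642 ± 921 CPM and Mir541 at 11371 ± 1624 CPM. Mir487b shares 20 bases with Mir376b, so its level is uncertain. Mir127 and Mir431 are known to lie antisense to the retrotransposon-like gene Rtl1. The listed genes spread over 184 kb of chromosome 12, from 109563692 to 109747960 in mm10. Levels varied widely within the cluster, since Mir1197, in the same array as Mir411, had only 18 counts in each library. Members went both ways between the libraries, with 21 higher in library 2, 20 higher in library 1 and 12 not passing the counting test. Together the Dlk1-Dio3, myomiR and let-7 lists accounted for 58.8% ± 0.624 of the counts. Shares leave out the multimapping reads, and that loss can differ between lists. Of the 58 Dlk1-Dio3 genes, 7 share 20 bases or more with another counted gene, against 6 of 12 myomiR and 6 of 12 let-7 genes. The order of the list shares therefore holds for counted reads only.

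**Figure D2:**
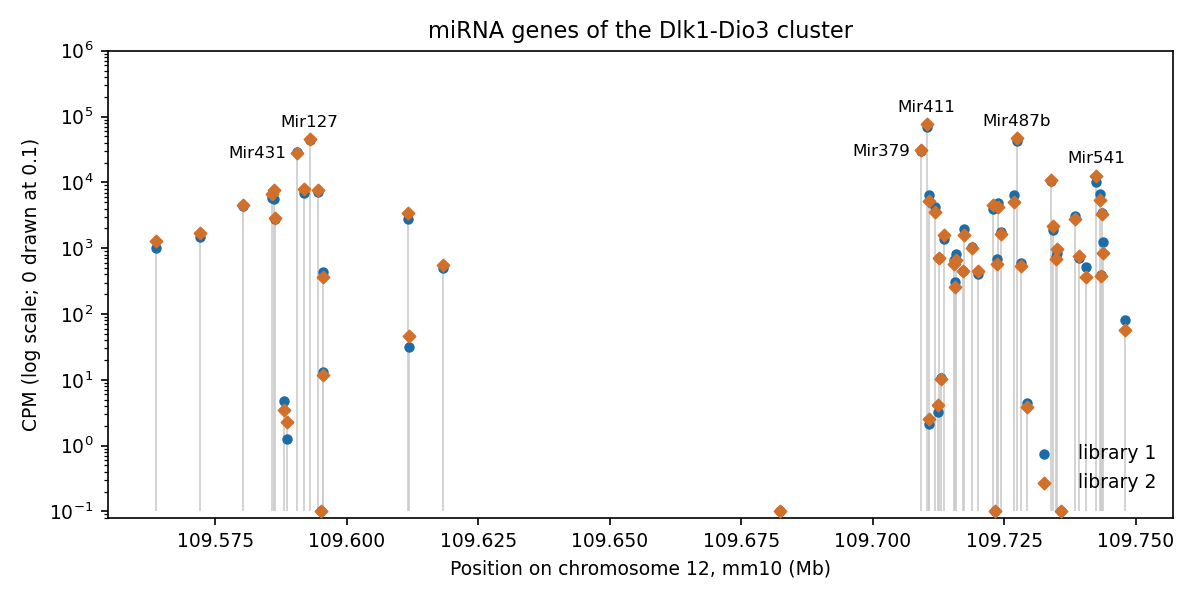
Level of each listed Dlk1-Dio3 gene (CPM, log scale, genes without counts drawn at 0.1) against its position on chromosome 12 in mm10 (Mb), with circles for library 1 and diamonds for library 2 and grey lines marking positions. Abundant genes such as Mir127 and Mir411 stand beside genes with under 10 CPM, and the libraries lie close together at most positions.

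The other families and clusters ranged widely in level. The X-linked Mir322-Mir503 cluster, whose members include the miR-15/16 relatives Mir322 and Mir503, held 3.38% ± 0.106 (SD, n = 2) with all 7 genes detected, led by Mir322 at 22057 ± 1806 CPM, Mir351 at 6990 ± 645 CPM and Mir542 at 2835 ± 29.3 CPM. The mir-23/27/24 clusters held 4.10% ± 0.377, mostly from Mir23b at 21631 ± 1348 CPM and Mir23a at 14453 ± 1741 CPM, while Mir27b was at 4139 ± 594 CPM. Hox-cluster miRNA genes held 1.81% ± 0.119, with Mir196b at 9580 ± 95.7 CPM, Mir10b at 5850 ± 1010 CPM and Mir10a at 1372 ± 55.8 CPM. Mir483, in an intron of the growth factor gene Igf2, reached 3695 ± 14.6 CPM, while Mir675, cut from the imprinted H19 transcript, reached 42.9 ± 3.55 CPM. The Mir17-92 cluster and its paralogs, associated with proliferation, held 0.649% ± 0.00440, led by Mir17 at 2216 ± 6.27 CPM, Mir93 at 1231 ± 32.5 CPM and Mir20a at 878 ± 4.41 CPM. The mir-30 family held 1.25% ± 0.146 with Mir30d at 5951 ± 541 CPM, Mir30a at 4281 ± 556 CPM and Mir30e at 2093 ± 395 CPM. The mir-26 family held 1.13% ± 0.126, nearly all from Mir26b at 11150 ± 1321 CPM, since Mir26a-2 was at 171 ± 57.8 CPM and Mir26a-1 at 5.10 ± 0.612 CPM. The mir-181 family held 0.232% ± 0.00360, with Mir181c at 795 ± 62.9 CPM, Mir181d at 704 ± 4.22 CPM and Mir181b-2 at 403 ± 113 CPM. The mir-29 family, which targets collagen transcripts, held only 0.0156% ± 0.00110, with Mir29a at 94.1 ± 8.71 CPM, Mir29c at 57.0 ± 2.89 CPM and Mir29b-1 at 2.67 ± 0.469 CPM. Mir221 at 95.8 ± 10 CPM and Mir222 at 15.6 ± 1.75 CPM, a pair expressed in proliferating myoblasts, together held 0.0111% ± 0.00120. Mir23a, Mir23b, Mir27a, Mir27b, Mir26a-1, Mir26a-2, Mir181b-2, Mir29b-1 and Mir29c each share 20 bases or more with another counted gene, which makes their levels uncertain. Mir30e overlaps another counted gene on the opposite strand, and its count was 0 when strand was ignored.

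Genes known as markers of other cell types were present at widely different levels. Mir126a, an endothelial gene in Egfl7, reached 25725 ± 5365 CPM, and Mir143, a smooth muscle gene, reached 26778 ± 2565 CPM, whereas its cluster neighbour Mir145a was at 527 ± 25.7 CPM. Connective tissue and cartilage markers held 0.483% ± 0.0831 (SD, n = 2), led by Mir214 at 3127 ± 616 CPM, Mir140, a cartilage gene in Wwp2, at 1576 ± 207 CPM, and Mir199b at 71.5 ± 7.25 CPM. Leukocyte markers held 0.0833% ± 0.0255, with Mir146 at 301 ± 79.3 CPM, the myeloid gene Mir223 at 257 ± 104 CPM and the haematopoietic gene Mir142 at 128 ± 46.8 CPM. Erythroid markers held 0.0108% ± 0.00160, with Mir451a at 83.1 ± 16.9 CPM and Mir144 at 25.1 ± 0.873 CPM. Epithelial and epidermal markers held 0.0381% ± 0.00820, led by Mir203 at 224 ± 31.3 CPM, Mir183 at 34.0 ± 2.84 CPM and Mir205 at 31.5 ± 16.4 CPM. Liver and gut markers held 0.0546% ± 0.0463, and the liver gene Mir122 alone made up 91.0% of them at 497 ± 463 CPM, followed by Mir194-2 at 15.6 ± 1.46 CPM and the endocrine gene Mir375 at 15.2 ± 1.38 CPM. Neural and glial markers held 0.0346% ± 0.000561, of which 97.4% was Mir338 at 337 ± 12.2 CPM. Only Mir338 and Mir219a-2 of the 10 neural genes were detected. When strand was ignored, Mir126a fell to 0.831 CPM and Mir451a, Mir142, Mir338 and Mir219a-2 to 0, because each overlaps a counted gene on the opposite strand. Levels of Mir146, Mir199b, Mir194-2 and Mir219a-2 are uncertain because each shares 20 bases or more with another counted gene. Of the 21 lists, the neural list had the lowest median level at percentile 94.4 of 10000 random lists drawn from all counted genes, but it was at 42.6 in library 1 alone and 96.9 in library 2 alone. Of the 2202 counted genes, 1462 had no count, and 1028 are not named Mir or Mirlet, of which 6 were detected. High percentiles against that background therefore say little about a list. With strand ignored the neural list was at percentile 40.1 and the endothelial list at 66.1. Against detected genes only, undetected members were left out of each list as well. The percentiles then ranged from 11.1 for liver and gut markers to 100 for the Dlk1-Dio3 list.

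The libraries ranked the genes alike. Across the 335 detected genes, log2(CPM + 0.5) had a Pearson r of 0.991 (95% bootstrap interval over genes 0.988 to 0.994) and a Spearman rho of 0.988, where genes are not independent replicates. The ratio between libraries was below 1.5-fold for 284 detected genes (84.8%), among them Mir206, Mir411, Mirlet7i and Mir127. The common coefficient of variation beyond counting error was 22.1% (95% bootstrap interval over genes 17.3 to 26.6). By an exact two-sided counting test with Benjamini-Hochberg adjustment over the 335 genes, 186 genes differed between the libraries beyond counting error, 96 higher in library 2 and 90 higher in library 1, and 149 did not. With DESeq2 size factors the split was 81 higher in library 2 and 105 higher in library 1, and with library totals 104 and 83. Which library held more of the higher genes thus depended on the scaling. The counting test compares these libraries and no conditions.

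**Figure D3:**
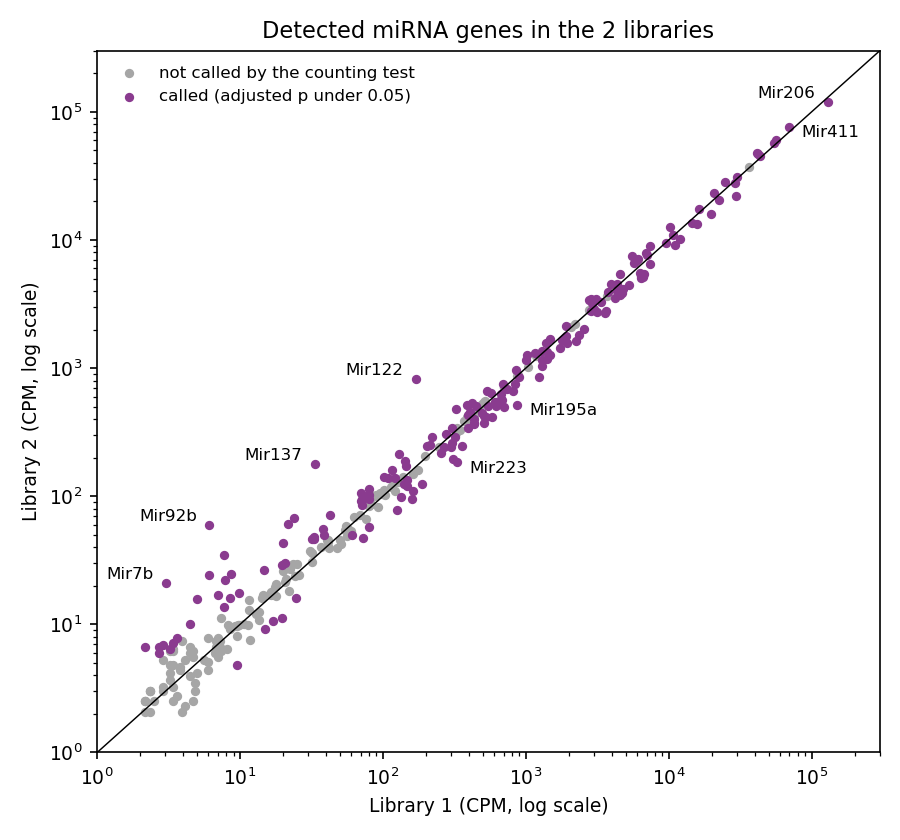
Level of each of the 335 detected genes in library 1 (horizontal, CPM, log scale) and library 2 (vertical, CPM, log scale), coloured by whether the counting test called a difference, with a line of equal level. Most points lie along the line, while Mir122, Mir137, Mir92b and Mir7b lie above it.

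The 20 detected genes that lay more than 2-fold apart were all higher in library 2, and none of that size was higher in library 1. Mir92b had the largest log2 ratio at 3.27 (95% counting interval 2.75 to 3.83), from 34 counts in library 1 and 260 in library 2. Mir7b, a gene of neuroendocrine tissue, followed at 2.76 (2.00 to 3.60), then Mir137, a gene of the nervous system, at 2.38 (2.15 to 2.62), Mir122 at 2.26 (2.16 to 2.37) and Mir760 at 2.15 (1.65 to 2.67). Mir122 had 942 counts in library 1 and 3573 in library 2, so its mean of 497 CPM describes neither library. In the other direction, the largest differences were in Mir223 at -0.87 (-0.99 to -0.75), Mir92-2 at -0.81 (-1.33 to -0.32), Mir142 at -0.79 (-0.96 to -0.62), Mir195a at -0.76 (-0.84 to -0.69) and Mir192, a liver and gut gene, at -0.71 (-1.30 to -0.15). Mir92-2 shares 22 bases with Mir92-1, so its ratio is uncertain.

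Leukocyte markers were lower in library 2 by list total, with a log2 ratio of -0.66 (95% counting interval -0.72 to -0.59), and 4 of the 5 detected members, including Mir223 and Mir142, were called lower. Erythroid markers were higher in library 2 at 0.28 (0.10 to 0.46), with Mir451a called at 0.40 (0.19 to 0.60) and Mir144 not called at -0.09. Endothelial Mir126a was also lower in library 2, at -0.45 (-0.46 to -0.44). Ignoring strand left 3 and 4 reads of Mir126a, too few for a ratio. Connective tissue markers were lower by total at -0.38 (-0.40 to -0.35), with Mir214 and Mir140 called and 2 of the 4 detected members not called. Mir214 made up 64.7% of that list. Of the 9 detected myomiR genes, 3 were lower in library 2, 1 was higher and 5 were not called. Mir206 was lower at -0.14, Mir499 at -0.33 (-0.38 to -0.27) and Mir208b at -0.60 (-0.75 to -0.45), and Mir486 was higher at 0.22 (0.03 to 0.42). Epithelial and epidermal markers were higher in library 2 at 0.42 (0.33 to 0.51), with 5 of 7 detected members called, among them Mir205 at 1.09 (0.74 to 1.44) and Mir203 at 0.26 (0.14 to 0.39). Smooth muscle markers were higher at 0.17 (0.16 to 0.18) by total, but Mir143 at 0.17 and Mir145a at -0.12 went opposite ways. The liver and gut list was higher at 1.98 (1.88 to 2.07), which rested on Mir122, since Mir192 was lower and Mir194-2, Mir375 and 1 further detected member were not called. The mir-23/27/24 clusters at -0.21 (-0.22 to -0.20), mir-30 at -0.26 (-0.28 to -0.24), mir-26 at -0.25 (-0.27 to -0.23) and Hox-cluster genes at -0.16 (-0.17 to -0.14) were lower by total. Members of mir-30 and mir-26 went both ways, since Mir30c-1 at 0.53, Mir30c-2 at 0.51 and Mir26a-2 at 0.68 were called higher in library 2. Mir30c-1 and Mir30c-2 share 28 bases, and Mir26a-2 shares 25 with Mir26a-1. Their levels and ratios are therefore uncertain, and so is the split within these families. Adjusted over the list alone, the number of called members changed in 4 of the 21 lists. It went from 4 to 3 for the myomiRs, where Mir486, the only member called higher in library 2, lost its call. Over all detected genes its adjusted p was 0.0462 by the counting test. The number went from 41 to 42 for Dlk1-Dio3, from 5 to 6 for mir-23/27/24 and from 4 to 5 for the leukocyte markers. The intervals cover counting error only, and with 1 animal per library no difference between the animals could be separated from differences in dissection or library preparation.

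**Figure D4:**
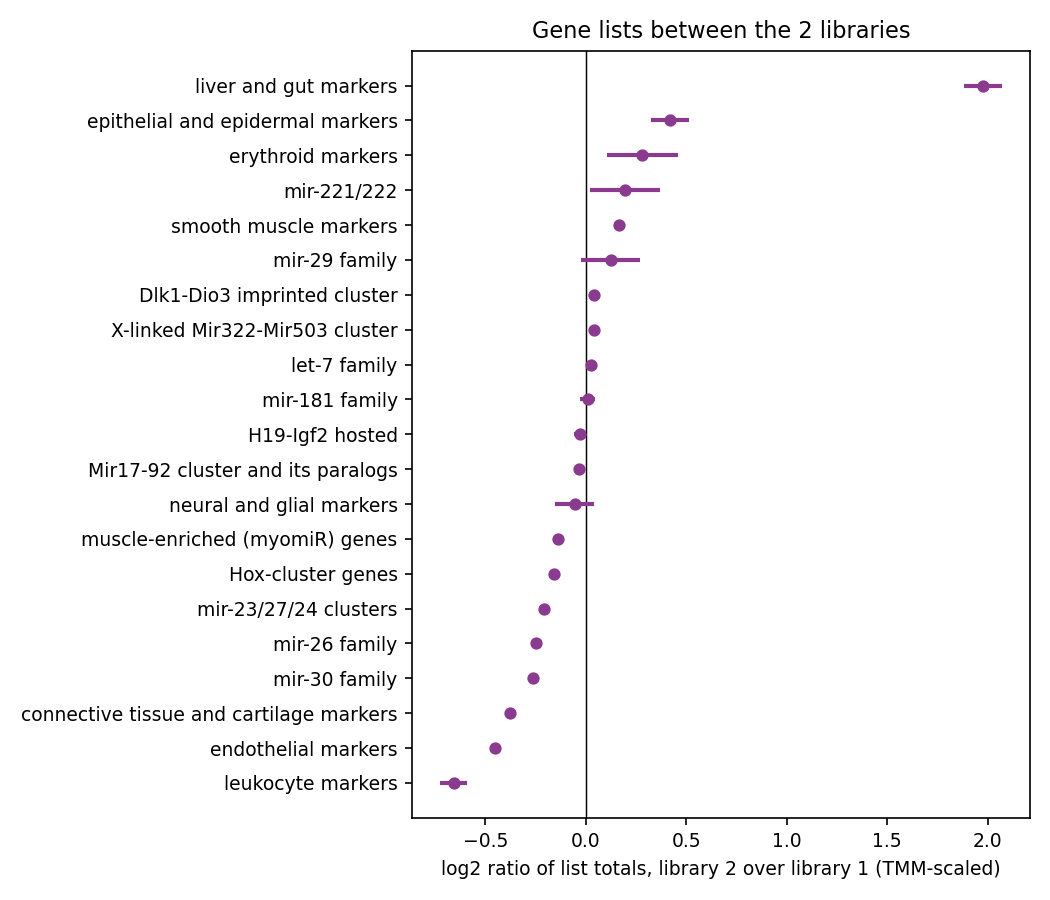
Log2 ratio of each list's total between the libraries (library 2 over library 1, scaled by TMM), as points with bars for the 95% counting interval, which is often narrower than the point. Liver and gut markers lie far to the right at 1.98 and leukocyte markers farthest to the left at -0.66.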

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

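The let-7 and Mir-named forms of the shared-stretch test and the multimapping ratio were chosen after the values were seen, and the forms over all counted genes before. Outside the columns used for the main values, the multimapping line held 36.9% of the reads in library 1 and 37.6% in library 2, above the limit of 3 counts that a count of 0 allows. Opposite-strand counts in genes that overlap no other counted gene came to 48 in library 1 and 47 in library 2. Single genes above 3 of these counts were Mir434 with 11 and Mir203 with 9 in library 1, and Mir434 with 13 and Mir708 with 4 in library 2. Mir434 and Mir708 are named here after their values were seen.

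Mir1a and Mir133a genes lay far below Mir206, with 131 counts for Mir1a-1, Mir1a-2, Mir133a-1 and Mir133a-2 together in library 1 and 114 in library 2. Mir1a-1 and Mir1a-2 share 28 bases, and Mir133a-1 and Mir133a-2 share 31. Reads lying within those stretches match more than 1 gene and so were left uncounted. How many such reads there were is unknown, so how far this explains the gap stays open. In the let-7 family, the 6 genes that share 20 bases with another counted gene had a median log2(CPM + 0.5) that differed by -6.16 from that of the other 6, p = 0.0130 by an exact two-sided permutation test over 924 splits. Some let-7 genes are neighbours, such as Mirlet7a-1 and Mirlet7f-1 on chromosome 13, and are not independent. With the form chosen after the values were seen, that p-value is a description only. The let-7 comparison was 1 of 6 forms of the test. Over genes named Mir or Mirlet the difference was -0.47, permutation p = 0.0025, with medians near the floor and 28.8% of sharing against 27.8% of other genes detected. Over all counted genes 6.99% against 23.2% were detected. Only 260 of those 1087 sharing genes are named Mir or Mirlet, against 914 of the 1115 others. Genes with other names were rarely detected, so that gap cannot be assigned to shared stretches. Lower expression than Mir206 stays open and cannot be told apart from missing reads, because the multimapping reads were at least 5.33 times the Mir206 count and their genes are unknown, and no biological explanation was tested.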

How the results depend on the processing

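Alternatives for the log2 ratios of list totals, for shared stretches among genes named Mir or Mirlet and in let-7 genes, and for the neural list without Mir338 were chosen after seeing the data. Genes called by the counting test numbered 165 to 198 under every alternative against 186, with 155 to 179 of the same genes called. Calls higher in library 2 made up 51.6% with TMM, 43.5% with DESeq2 size factors and 55.6% with library totals. The Pearson r and the coefficient of variation stayed within their bootstrap intervals under every alternative run. Counting every gene with 1 count in either library gave 740 genes in place of 335 and a Spearman rho of 0.903, because genes near the floor enter. Over all counted genes, those sharing a stretch of 20 bases had a median log2(CPM + 0.5) that differed by -0.22 from the others, and by -0.27 and -0.22 at 18 and 24 bases, p = 1.0e-05 each by a two-sided permutation test, the smallest 100000 draws can give. Both medians lay near the floor. At 20 bases, 260 of the 1087 sharing genes are named Mir or Mirlet, against 914 of the 1115 others. Of the 1028 genes with other names 6 were detected, so these contrasts mix shared stretches with the kind of gene. Neighbouring genes differed by 2.35 at 50 kb in place of 2.28. No paired analysis was possible because there is 1 group.

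Ignoring strand removes reads in places where counted genes overlap, which takes 26 of the 335 detected genes below the threshold and raises the shares of the others. With unstranded counts the 10 most abundant genes held 58.1% in place of 54.1%. List shares became 14.3% for myomiRs, 13.7% for let-7, 35.4% for Dlk1-Dio3, 0.426% for H19-Igf2, 3.85% for Mir322-Mir503, 0.739% for Mir17-92, 0.0177% for mir-29, 0.264% for mir-181, 4.65% for mir-23/27/24, 1.29% for mir-26, 0.0127% for Mir221-Mir222, 2.06% for Hox genes and 3.11% for smooth muscle. Shares fell to 0.0029% for erythroid, 8.31e-05% for endothelial and 0.000164% for neural markers, whose leading genes overlap another counted gene, and by less than 1 SD to 1.19% for mir-30 and 0.0804% for leukocyte markers. The Dlk1-Dio3 share rose although its member Mir337, named after its values were seen, dropped to 5 and 18 reads. The log2 ratio of list totals changed sign for 5 lists: let-7 at -0.0047, mir-181 at -0.02 from 0.01, erythroid markers at -0.12 from 0.28, endothelial markers at 0.73 from -0.45 and neural markers at 2.77 from -0.06. The endothelial value rests on 3 and 4 reads of Mir126a, and the erythroid and neural values lack Mir451a and Mir338, so these say little about the ratios. The let-7 ratio was 0.02 in the main setting and -0.0073 with DESeq2 size factors, and that of mir-181 was -0.02 with DESeq2 size factors, so neither has a direction.

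List percentiles with unstranded counts were 99.91 for myomiRs, 99.5 for H19-Igf2, 97.8 for mir-29, 99.90 for mir-30, 100 for mir-181 and mir-23/27/24, 95.5 for Mir221-Mir222, 81.4 for erythroid, 99.96 for leukocyte, 66.1 for endothelial, 99.5 for smooth muscle, 99.6 for connective, 99.97 for epithelial, 40.1 for neural and 99.8 for liver and gut markers. For ranks against detected genes only, undetected genes were left out of the background and of the lists. The neural value there rests on 2 genes and the endothelial value on 1. The percentiles were 36.0 for myomiRs, 99.7 for let-7, 70.5 for H19-Igf2, 95.3 for Mir322-Mir503, 92.2 for Mir17-92, 37.5 for mir-29, 80.6 for mir-30, 77.3 for mir-181, 96.1 for mir-23/27/24, 58.2 for mir-26, 25.6 for Mir221-Mir222, 93.7 for Hox genes, 27.9 for erythroid, 50.3 for leukocyte, 96.7 for endothelial, 95.1 for smooth muscle, 71.6 for connective, 14.9 for epithelial, 24.9 for neural and 11.1 for liver and gut markers. With each library alone they ranged from 99.30 to 99.36 for H19-Igf2, 97.2 to 97.4 for mir-29, 99.93 to 99.94 for leukocyte, 99.38 to 99.39 for smooth muscle, 99.64 to 99.70 for liver and gut, 99.96 to 99.98 for mir-181, 98.4 to 98.7 for mir-26 and 99.57 to 99.59 for connective markers. The neural percentile was 42.6 without library 2 and 96.9 without library 1, since 8 of its 10 genes were not detected and most counts are few. Depth limits any statement on genes below 0.692 CPM.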

Other observations

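The neural list without Mir338, the weighing of lists and of Mir192 as signs of other tissues, and the choice of neighbours given as examples came after the values were seen. The ratios of whole lists and the test of neighbouring genes were planned.

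Some further genes among the 20 that lay more than 2-fold apart are given here as values. Gm26117, Mir135b, Mir702, Mir3107, n-TSaga9, Mir3475 and Mir181b-1 were also among the 20, and their values are left out. Except for Mir219a-2, all these genes are named after their values were seen, so the values given do not represent the 20. Mir383 had a log2 ratio of library 2 over library 1 of 1.98 (95% counting interval 1.41 to 2.58), Mir138-1 of 1.45 (1.14 to 1.78), Mir138-2 of 1.5 (0.99 to 2.02) and Mir488 of 1.29 (0.34 to 2.29). Mir449a, known from multiciliated epithelium, was at 1.48 (1.18 to 1.79) and Mir429, an epithelial gene, at 1.48 (0.95 to 2.03). Mir219a-2, a gene of myelinating glia, was at 1.61 (0.60 to 2.72). It was the only called gene on the neural list, where 2 of the 10 genes were detected and the other 8 were not tested.

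The marker lists that differed between the libraries were weighed against RNA of other tissues. More blood in library 2 stays open, since its marker lists went apart: the leukocyte list was lower there at -0.66 (-0.72 to -0.59) and the erythroid list higher at 0.28 (0.10 to 0.46). The erythroid value rested on Mir451a at 0.40, since its neighbour Mir144 was at -0.09 (-0.47 to 0.28) and not called. More skin and neural RNA in library 2 stay open too, since the epithelial list at 0.42 is part of the pattern itself and the neural list without Mir338, at 1.60 (0.91 to 2.34), was formed after its members were seen, so neither value tests its source. That neural value rests on 25 and 60 counts and on leaving out the most abundant member, with which the list was at -0.06 (-0.15 to 0.04). Liver RNA stays open: Mir122 was higher, Mir192 was lower at -0.71, and no liver profile was used here to say how much Mir192 such RNA would bring, while reads carried over from other sequenced libraries and differences between the animals were not tested.

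Adjacent genes on 1 strand may have like levels because many are cut from a shared transcript. In 112 pairs of detected neighbours under 10 kb apart, the median absolute difference of log2(CPM + 0.5) was 2.28, against 3.76 for random pairs (95% range 2.98 to 4.62), p = 2.0e-04 by a two-sided permutation test with 10000 draws, the smallest they can give. The difference between neighbours was still large, as in Mir23a and Mir27a, whose ratio was 25.3 ± 0.177 (SD, n = 2), and in Mir143 and Mir145a, at 51.0 ± 7.36. Mir23a and Mir27a each share 20 bases with another counted gene, so their ratio is uncertain. Pairs within the Dlk1-Dio3 cluster share a locus and are not independent.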
